A study of Homo sapiens with 77 samples.

How the data were processed

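Transcript levels were measured on Affymetrix expression arrays in tissue taken by laser microdissection from frozen sections. There were 31 samples of cancer stroma and 32 of tumor epithelium from high-grade serous ovarian carcinomas, 8 of normal ovarian stroma and 6 of ovarian surface epithelium. Per the labels, total RNA went through a 2-cycle amplification and a biotin label before hybridization. The deposited table held 54675 probe sets on 77 arrays as log2 values, which per the submitters' processing notes came from RMA (version not stated). In the values, each of the 54675 probe sets had a median of 0 over the 77 arrays, so the authors centred each probe set and a value gives the log2 distance from that median. The log base is not stated in the labels and was taken as 2 from the range of the values. The absolute signal was lost in the centring, so neither the signal over background nor detection can be given, and the number of arrays limits the precision.

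All steps were run in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). The 62 control probe sets, 11721 probe sets with no gene symbol and 1801 with several symbols were set aside, as were 59 probe sets of genes on the Y chromosome and of the X inactivation transcripts. A level filter and a choice of probe set by the highest mean had been planned and could not be made on centred values. Each gene was therefore read from its probe set with the largest SD over the 77 arrays, with no filter, which left 19740 genes. This choice favours probe sets with large differences, and the mean of a gene's probe sets was run beside it. In tests on simulated data, with 100 genes planted at a change of 2.5 on the log2 scale, 97 of them passed between the stroma groups and 88 between normal stroma and surface epithelium, and none had the wrong sign. At a planted change of 1.5, 84 passed between the stroma groups, 62 between normal stroma and surface epithelium and 65 for the difference of the cancer-normal differences.

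Groups were taken from the sample labels. The comparisons were cancer stroma against normal stroma, tumor epithelium against surface epithelium, cancer stroma against tumor epithelium, normal stroma against surface epithelium, and the difference between the cancer-normal differences of stroma and epithelium. Each was fitted with limma (lmFit and eBayes). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the 19740 genes and a change of at least 2-fold. The titles give 28 sample numbers to both a cancer stroma and a tumor epithelium array, and 7 cancer arrays have no partner. Regions with 1 number were taken as 1 specimen and entered as a random block (duplicateCorrelation) in the gene-by-gene fits that held both cancer groups. As a check of this pairing over the 5000 most variable genes, with the group means removed, 21 of the 28 pairs had r over 0.1 (median r 0.285, against -0.00779 in other combinations), and 16 stroma arrays lay closest to the epithelial array with their own number. Donors of the normal groups are not stated, and whether any normal stroma and surface epithelium samples came from the same ovary is not known. The p-values therefore measure the spread between samples as labelled.

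30 gene lists were fixed before the data were examined. They held markers of activated fibroblasts, extracellular matrix genes, matrix remodelling enzymes, the TGF-beta pathway, TGF-beta response genes, versican and hyaluronan genes, secreted growth factors, cytokines and chemokines, WNT modulators, mesenchymal transcription factors, ovarian stromal and steroid genes, epithelial markers, serous carcinoma markers, mesothelial and surface epithelium markers, proliferation genes, homologous recombination genes, interferon response genes, MHC class II genes, markers of T and NK cells, of B and plasma cells, of macrophages, of endothelium, of smooth muscle and pericytes, of adipocytes, of red cells, of ciliated cells and of granulosa and luteal cells, immediate early genes, hypoxia response genes and complement genes. Some genes stood in more than 1 list, among them 13 of the 20 measured TGF-beta response genes. List members without a probe set under their symbol were left out as not measured under that name. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a comparison, and beside it with an estimated correlation and with fry. For cancer stroma against tumor epithelium these list tests used the 28 paired specimens alone, with the specimen as a fixed block. For the difference between the cancer-normal differences they used all arrays without a block, so they ignored the pairing. Members that passed were also counted with the p-values adjusted over the list alone.

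The genes to be named were set by a rule written before the data were examined. For each comparison it took the 8 genes that passed with the largest rise and the 8 with the largest fall, up to 4 passing members of each list with the largest change and up to 2 of the other direction, and VCAN, MFAP5, TGFBR2, TGFB1, CD44, FGF18 and FGF1 with any value, since the series concerns a fibroblast signature. For the difference between the cancer-normal differences it took the 5 largest each way, and for the genes higher in cancer stroma in both of its comparisons the 12 with the largest smaller fold change. Of these, the text gives the ones with the largest change in each list.

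Array quality was read from the control probe sets: GAPDH and ACTB at the 3′ and 5′ end, the mean of 18 hybridization spikes, the mean of 27 poly-A spikes, and 18S ribosomal RNA. Groups were compared on these by 2-sided permutation tests, exact where the groups had 6 against 32 or 8 arrays and with 100000 resamples elsewhere, in a family of 36 tests. Alternatives fixed before the data were examined were the mean of all probe sets of a gene, the exclusion of probe sets ending in _x_at or _s_at, a further quantile normalization, array weights, eBayes with trend and robust, the GAPDH 3′ minus 5′ difference as a covariate, no fold threshold, limma's treat against 1.5-fold, other treatments of the replicate block, and leaving out each normal array in turn. Alternatives chosen after seeing the data were array medians set to 0, the genes with an SD above the median SD, the exclusion of 4 cancer arrays with an SD over 0.9, the average of the 2 closest cancer stroma arrays, and the hybridization spikes as a covariate. That exclusion was made among the cancer arrays only, and 4 normal stroma arrays and 1 surface epithelium array over the same SD were kept.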

Results

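The 77 arrays came from microdissected cancer stroma (31), tumor epithelium (32), normal ovarian stroma (8) and ovarian surface epithelium (6), the thin cell layer that covers the ovary. Values are log2 signals relative to each probe set's median, and differences between groups are log2 fold changes with their standard error (SE). Control probe sets differed between the groups. The GAPDH 3′ control, read near the end of the transcript that amplification keeps, had a mean of -2.10 ± 0.39 (SD, n = 8) in normal stroma and 0.05 ± 0.81 (SD, n = 31) in cancer stroma (permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted p = 3.27e-05 over 36 tests). It had a mean of -0.03 ± 0.18 (SD, n = 6) in surface epithelium and -0.04 ± 0.59 (SD, n = 32) in tumor epithelium (exact permutation p = 0.968). The GAPDH 3′ minus 5′ difference, which grows as RNA is shortened, was 1.78 ± 0.25 (SD) in normal stroma and 1.54 ± 1.18 in cancer stroma (permutation p = 0.581). It was -0.57 ± 0.63 in tumor epithelium and -1.06 ± 0.24 in surface epithelium. The hybridization spikes, which enter every array at the same amount, had means of 1.55 ± 0.34 (SD) in normal stroma, 0.76 ± 0.86 in cancer stroma, 0.02 ± 0.23 in surface epithelium and -1.63 ± 0.64 in tumor epithelium. Between surface and tumor epithelium these spikes differed (exact permutation p = 9.06e-06), as did array SD (8.33e-06), array median (3.62e-07) and 18S (0.0157). The poly-A spikes did not overlap (-0.24 to -0.18 against -0.11 to 0.13, exact permutation p = 3.62e-07). GAPDH 3′ minus 5′, ACTB 3′ minus 5′ and GAPDH 5′ did not differ clearly (p = 0.0826, 0.145 and 0.255 in the same test).

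**Figure D1:**
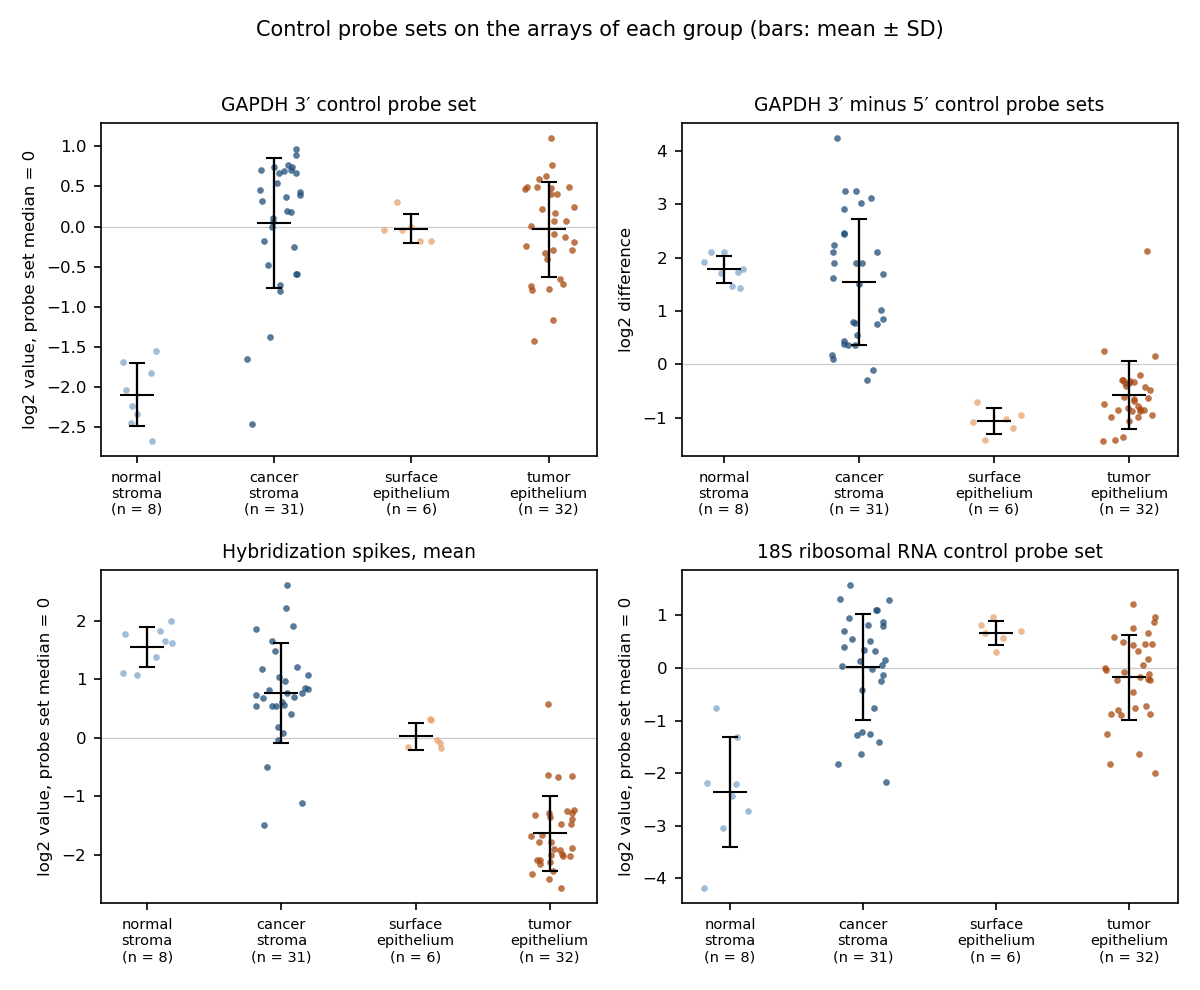
Control probe sets on each of the 77 arrays (points) in the 4 groups, with the mean and SD of each group as bars, in log2 units relative to each probe set's median or as a log2 difference. The normal stroma arrays had the lowest mean of the GAPDH 3′ control (-2.10) and the highest mean of the hybridization spikes (1.55).

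The first comparison asked which transcripts of the stroma around the carcinomas differ from those of stroma in ovaries without cancer. Most, though not all, of the listed matrix and fibroblast activation genes were higher in the 31 cancer stroma arrays than in the 8 normal stroma arrays. Their counts and list tests are given in the next paragraph. COL11A1, a minor fibrillar collagen, rose by 5.71 ± 0.87 (log2 fold change ± SE, adjusted p = 2.59e-06 in limma) and lay above the normal stroma median in 29 of 31 cancer stroma arrays. POSTN, which encodes the matrix protein periostin, rose by 5.12 ± 0.79 and VCAN, which encodes the proteoglycan versican, by 4.50 ± 0.72, each above that median in 31 of 31 arrays. SPP1, the secreted phosphoprotein osteopontin, rose by 5.08 ± 0.85, and EPCAM, an adhesion molecule of epithelial cells, by 5.01 ± 0.75. Of 19740 genes, 4862 were higher and 861 lower in cancer stroma.

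Of the 17 markers of activated fibroblasts, 14 rose and 3 did not pass (14 adjusted over the list alone), among them CTHRC1 (4.56 ± 0.75) and SULF1 (3.64 ± 0.78). Of 27 extracellular matrix genes, 20 rose and 7 did not pass (22 rose adjusted over the list alone), with COL5A2 at 4.90 ± 0.77 and COL3A1 at 4.75 ± 0.65. Of 27 matrix remodelling genes, 18 rose and 1 fell (the same counts adjusted over the list alone). PLAU, the urokinase protease, rose by 3.97 ± 0.72 and LOXL1, a collagen crosslinking enzyme, by 3.79 ± 0.58, while P4HA3 fell by 1.05 on the log2 scale. TGF-beta response genes rose in 17 of 20 cases (17 adjusted over the list alone), with COMP at 4.65 ± 1.11 and COL1A1 at 4.32 ± 0.59. In other lists stood 13 of these 20 genes. TGF-beta pathway genes rose in 8 of 16 cases and fell in 1 (8 and 1 adjusted over the list alone), with the latency protein LTBP3 at 3.59 ± 0.51, LTBP2 at 2.32 ± 0.43 and the receptor TGFBR3 at -1.70 ± 0.68. Camera called these 5 lists up with the preset correlation, and each call was lost at adjusted p = 0.505 with an estimated correlation. MFAP5, a microfibril protein, rose by 3.36 ± 1.06, TGFBR2, the type II TGF-beta receptor, by 1.61 ± 0.57, CD44, a hyaluronan receptor, by 2.49 ± 0.62, and the growth factor FGF18 by 2.43 ± 0.50. With the mean of all probe sets of a gene TGFBR2 (0.42), CD44 (0.30) and FGF18 (0.58) did not pass, nor did P4HA3 (-0.35). TGFB1 at 0.47 ± 0.21 (adjusted p = 0.0538) and FGF1 at 0.70 ± 0.38 (adjusted p = 0.113) did not pass, and FGF1 passed with array weights (1.004). The normal stroma arrays with these lower matrix values also had the lower GAPDH 3′ signal (-2.10 against 0.05).

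Some immune lists and the stress lists also rose. All 12 macrophage markers were higher in cancer stroma (12 adjusted over the list alone), with the complement component C1QB at 3.69 ± 0.62 and CD14 at 3.25 ± 0.52. Of 9 MHC class II genes 7 rose (HLA-DPA1 3.22 ± 0.65, HLA-DPB1 2.63 ± 0.44) and of 9 complement genes 5 (C3 4.23 ± 0.47, CFB 3.05 ± 0.56). Of 16 immediate early genes, which also move with tissue handling, 11 rose (KLF6 3.86 ± 0.50, CCN1 3.09 ± 0.50) and of 11 hypoxia response genes 8 (VEGFA 2.93 ± 0.51, LDHA 2.86 ± 0.36). The counts in these 4 lists were the same adjusted over each list alone. Camera called these 5 lists up, and each call was lost at adjusted p = 0.505 with an estimated correlation. Interferon response genes rose in 12 of 17 cases (GBP1 3.96 ± 0.57, IFI44 3.36 ± 0.59) and proliferation genes in 15 of 25 (RRM2 2.96 ± 0.79, TYMS 2.84 ± 0.58), as many as adjusted over the list alone. Epithelial markers rose in 7 of 16 cases (CD24 3.26 ± 0.93, ESRP1 3.15 ± 0.58; 7 adjusted over the list alone), and serous carcinoma markers in 10 of 20 (SLPI 3.32 ± 0.68, WFDC2 2.26 ± 0.51; 11 adjusted over the list alone). The camera calls of these 4 lists were lost too, at adjusted p = 0.582 for proliferation and 0.597 for the others with an estimated correlation. Adipocyte markers fell in 3 of 7 cases (FABP4 -1.95 ± 0.55, LEP -1.83 ± 0.29; 3 adjusted over the list alone), a call lost at adjusted p = 0.505 with an estimated correlation. Of the 15 camera calls between the stroma groups, 7 held among the genes with an SD above the median SD. VEGFA (0.87), CFB (0.90), TYMS (0.88) and WFDC2 (0.64) no longer passed with the mean of all probe sets of a gene. Without probe sets ending in _x_at or _s_at HLA-DPB1 (0.14), IFI44 (0.24) and GBP1 (1.57) did not, and CFB (-1.24) had the opposite sign.

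The 15 other lists had no camera call between the stroma groups. Cytokines and chemokines rose in 6 of 19 cases (CXCL14 3.87 ± 1.04, CXCL8 2.12 ± 0.65; camera adjusted p = 0.129). WNT modulators rose in 6 of 12 (SFRP2 4.52 ± 1.18, FRZB 1.99 ± 0.56; 0.352) and mesenchymal transcription factors in 3 of 7 (SNAI2 2.88 ± 0.53, PRRX1 1.86 ± 0.70; 0.352). Secreted growth factors went both ways, with 7 of 22 up and 4 down (IGF1 2.39 ± 0.65, WNT2B -1.91 ± 0.43; 0.818). Versican and hyaluronan genes also did, with 5 of 12 up and 1 down (ADAMTS5 -1.91 ± 0.53; 0.237). Of 21 ovarian stromal and steroid genes 1 rose and 3 fell (OGN -3.01 ± 0.91, ADH1B -2.496 ± 1.03; 0.289; 0 and 2 adjusted over the list alone), and this list's median changed sign with array medians set to 0. Mesothelial and surface epithelium markers had 2 of 14 up and 2 down (GPM6A -3.14 ± 0.96, DAB2 1.99 ± 0.41; 0.647). Homologous recombination genes had 2 of 9 up and 1 down (XRCC2 -2.71 ± 0.42, RAD51C 1.39 ± 0.32; 0.462), and granulosa and luteal markers 1 of 5 up and 1 down (CYP19A1, the estrogen-forming aromatase, -3.25 ± 0.40, FST 1.85 ± 0.55; 0.289). Endothelial markers rose in 3 of 12 cases (PECAM1 1.60 ± 0.45, VWF 1.52 ± 0.48; 0.455) and smooth muscle and pericyte markers in 3 of 11 (MCAM 2.14 ± 0.48, ACTG2 2.03 ± 0.83; 0.344; 2 adjusted over the list alone). Of 13 T and NK cell markers 1 rose (CCL5 1.56 ± 0.58; 0.957; 0 adjusted over the list alone in limma, with 2 higher and 1 lower at an unadjusted p under 0.05). Of 4 red cell markers HBB, a haemoglobin chain, fell by 2.51 on the log2 scale (0.0538). In limma 0 of 8 B and plasma cell markers passed (0.352; 1 higher and 3 lower at an unadjusted p under 0.05) and 0 of 8 ciliated cell markers (0.323; 0 higher and 1 lower). FRZB (0.68), PRRX1 (0.73), RAD51C (0.78), PECAM1 (0.63), VWF (0.67), MCAM (0.86), ACTG2 (0.91) and CCL5 (0.69) no longer passed with the mean of all probe sets of a gene. FRZB (1.09) and HBB (-0.56) did not pass without probe sets ending in _x_at or _s_at.

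The largest falls in cancer stroma were TIMM8A, a mitochondrial import protein (-4.27 ± 0.42), ELMOD2 (-3.99 ± 0.44), ARHGEF7 (-3.93 ± 0.39), LINC00537 (-3.56 ± 0.50) and RALGAPA2 (-3.37 ± 0.32), each below the normal stroma median in at least 30 of 31 arrays. With the mean of all probe sets of a gene, the counts fell to 2541 higher and 354 lower, and 18 of the 76 named genes no longer passed, ELMOD2 (-0.54) and ARHGEF7 (-0.30) among them. ELMOD2, LTBP3, CXCL14, MCAM, CFB and TGFB1 had the opposite sign without probe sets ending in _x_at or _s_at.

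**Figure D2:**
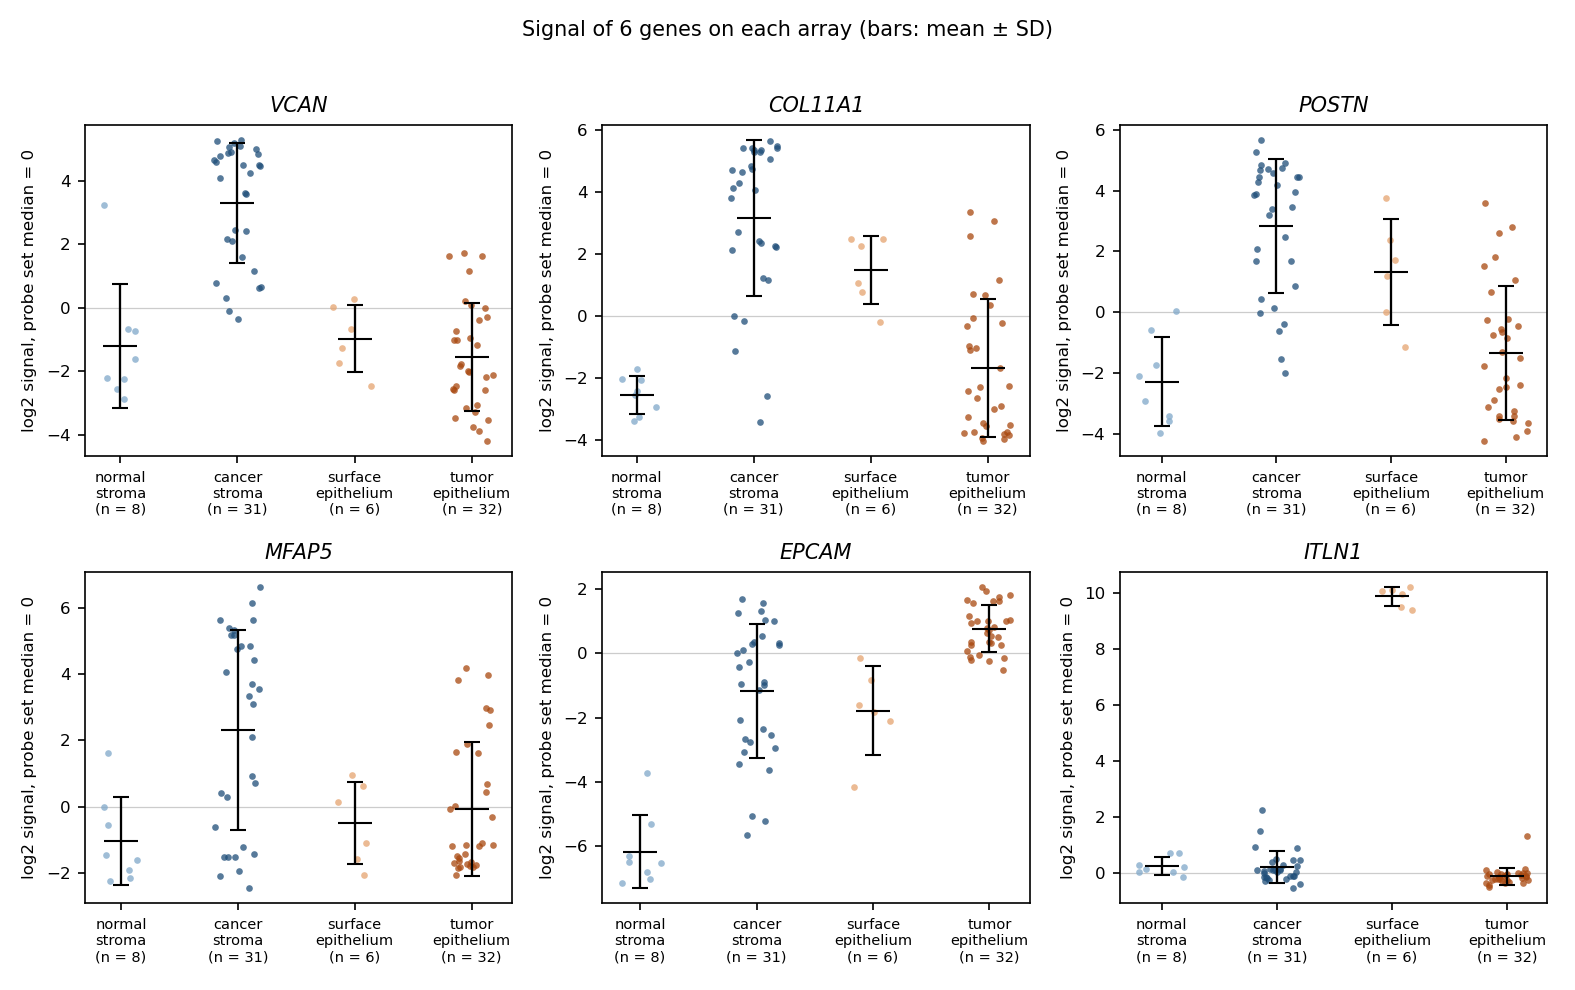
Log2 signal of 6 genes relative to each probe set's median on each of the 77 arrays (points), with the mean and SD of the 4 groups as bars. VCAN, COL11A1, POSTN and MFAP5 were highest on average in cancer stroma, EPCAM in tumor epithelium and ITLN1 in surface epithelium.

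The second comparison asked which transcripts of the carcinoma cells differ from those of normal ovarian surface epithelium. CD24, a glycoprotein of the cell surface, rose by 5.86 ± 0.57 (log2 fold change ± SE, adjusted p = 4.85e-11 in limma) in the 32 tumor epithelium arrays against the 6 of surface epithelium. MECOM, a transcription factor, rose by 5.47 ± 0.47 and CP, which encodes ceruloplasmin, by 5.40 ± 0.58, each above the surface epithelium median in 32 of 32 arrays. ITLN1, the mesothelial lectin omentin, was lower by -9.99 ± 0.14 and BNC1, a transcription factor of mesothelium, by -7.66 ± 0.44, each below that median in 32 of 32 arrays. HBB was lower by -8.97 ± 0.39, and the other large falls included BCHE (-8.30 ± 0.19), ADH1B (-8.26 ± 0.28) and ABCA8 (-7.80 ± 0.15). Of 19740 genes, 1414 were higher and 4460 lower in tumor epithelium, so 24.1% of those that passed were higher. After a further quantile normalization this share was 40.9% (1696 and 2452). With the hybridization spikes as a covariate, 850 of the 1414 and 3571 of the 4460 still passed. The poly-A spikes did not overlap between these groups, so array quality as a source of part of these differences stays open.

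Mesothelial and surface epithelium markers fell in 11 of 14 cases (11 adjusted over the list alone), among them ALDH1A2 at -6.51 ± 0.36, and camera called this list down also with an estimated correlation (adjusted p = 1.26e-06). It was the only list of the 30 in this comparison whose call held with an estimated correlation. Serous carcinoma markers rose in 13 of 20 cases and fell in 1 (SOX17 4.31 ± 0.43, FOLR1, a folate receptor, 4.65 ± 0.61, MSLN -2.33 ± 0.41; adjusted p = 0.399 with an estimated correlation). Proliferation genes rose in 18 of 25 (TOP2A 3.29 ± 0.55, CDK1 2.69 ± 0.61; adjusted p = 0.619 with an estimated correlation). Homologous recombination genes rose in 7 of 9 and fell in 1 (BLM 2.22 ± 0.18, RAD54L 1.66 ± 0.15, RAD51C -1.11 ± 0.32; adjusted p = 0.452 with an estimated correlation). Epithelial markers rose in 9 of 16 and fell in 2 (CLDN3 3.12 ± 0.41, ELF3 2.99 ± 0.39, KRT19 -2.25 ± 0.43; adjusted p = 0.619 with an estimated correlation). In these 4 lists the counts adjusted over the list alone were the same.

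Several stromal and immune lists were lower in tumor epithelium than in surface epithelium, and others were not: T and NK cell markers had 1 of 13 higher and 1 lower, B and plasma cell markers 1 of 8 higher, smooth muscle and pericyte markers 2 of 11 higher and 2 lower, and cytokines and chemokines 2 of 19 higher and 1 lower. Of 27 extracellular matrix genes 16 fell and 1 rose (DCN, the proteoglycan decorin, -5.80 ± 0.67, COL8A1 -5.05 ± 0.73, COMP 1.02 ± 0.41; adjusted p = 0.747 with an estimated correlation). Secreted growth factors fell in 11 of 22 cases (WNT2B -5.82 ± 0.32, PDGFD -5.76 ± 0.24; adjusted p = 0.0723 with an estimated correlation). Ovarian stromal and steroid genes fell in 11 of 21 cases (ALDH1A1 -5.26 ± 0.26, OGN -7.29 ± 0.36; 0.0567 in the same test), and mesenchymal transcription factors in 5 of 7 (PRRX1 -3.76 ± 0.52, ZEB1 -3.67 ± 0.44; 0.619). TGF-beta pathway genes fell in 8 of 16 cases and rose in 1 (TGFBR2 -3.20 ± 0.36, SMAD4 -2.39 ± 0.32, LTBP1 1.19 ± 0.43; adjusted p = 0.399 with an estimated correlation). All 12 macrophage markers fell (MS4A4A -4.30 ± 0.50, CD14 -3.85 ± 0.48; adjusted p = 0.573 with an estimated correlation), as did all 9 complement genes (C7 -4.16 ± 0.62, SERPING1 -3.74 ± 0.38; 0.0723) and 3 of 4 red cell markers (HBD -3.15 ± 0.36; 0.399). In each of these lists the counts adjusted over the list alone were the same as those over all genes. CD44 fell by 3.12 and FGF1 by 3.77 on the log2 scale. VCAN (-0.57 ± 0.70, adjusted p = 0.472), MFAP5 (0.44 ± 0.83, 0.648), TGFB1 (-0.15 ± 0.12, 0.262) and FGF18 (0.92 ± 0.50, 0.0974) did not pass, and FGF18 passed with the GAPDH covariate (1.14). Without probe sets ending in _x_at or _s_at, HBB and FOLR1 had the opposite sign, and with the mean of all probe sets of a gene the counts were 919 higher and 2419 lower. Among the genes with an SD above the median SD the camera calls of the matrix, TGF-beta pathway and mesenchymal factor lists were lost. With the mean of all probe sets CD44 (-0.45), KRT19 (-0.84), LTBP1 (0.92) and RAD51C (-0.54) no longer passed.

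The third comparison set the stroma of the carcinomas against their epithelium, with the specimen as a block. Of the sample numbers, 28 had both parts, and 7 arrays had no partner. C11orf96 was higher in the 31 cancer stroma arrays than in the 32 tumor epithelium arrays by 5.69 ± 0.31 (log2 fold change ± SE, adjusted p = 3.64e-24 in limma), DCN by 5.55 ± 0.36 and INHBA, a subunit of activin, by 5.40 ± 0.45, each above the tumor epithelium median in 31 of 31 arrays. VCAN was higher by 4.87 ± 0.40, also in 31 of 31 arrays. EGFR, the receptor of epidermal growth factor (-3.59 ± 0.29), PARD6B, a protein of epithelial polarity (-3.22 ± 0.25), and MUC1, an epithelial mucin (-2.69 ± 0.27), were lower in cancer stroma. Of 19740 genes, 2397 were higher and 763 lower, so 75.9% of those that passed were higher; after a further quantile normalization this share was 59.6% (2053 and 1389). The specimen correlation was 0.145. With the mean of all probe sets of a gene 10 of the 60 named genes no longer passed: EGFR (-0.91), FOLR1 (-0.64), CD44 (0.33), ESR1 (-0.26), SPON1 (0.12), CHEK1 (-0.69), MSR1 (0.64), PECAM1 (0.94), RGS5 (0.81) and FGF1 (0.75). C11orf96 (0.86) and C1S (0.02) did not pass without probe sets ending in _x_at or _s_at.

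Extracellular matrix genes were higher in cancer stroma in 25 of 27 cases (COL8A1 5.47 ± 0.40, FBN1 5.35 ± 0.30). TGF-beta response genes were higher in 16 of 20 (ACTA2, smooth muscle actin, 4.62 ± 0.31, COL1A1 4.56 ± 0.36) and secreted growth factors in 13 of 22 (PDGFD 3.30 ± 0.23, PDGFC 2.84 ± 0.27), with the same counts adjusted over each list alone. These were the 3 of 30 lists whose camera call held with an estimated correlation, each at adjusted p = 0.0483. Markers of activated fibroblasts were higher in 16 of 17 cases (PDGFRA 5.08 ± 0.26, COL11A1 4.85 ± 0.53; adjusted p = 0.0626 with an estimated correlation). Matrix remodelling genes rose in 17 of 27 and fell in 1 (LOX 4.30 ± 0.44, TIMP3 3.63 ± 0.38, MMP7 -1.31 ± 0.43) and mesenchymal transcription factors rose in 5 of 7 (ZEB1 4.81 ± 0.28, SNAI2 4.10 ± 0.29), both at adjusted p = 0.129 with an estimated correlation. TGF-beta pathway genes rose in 8 of 16 (LTBP2 3.44 ± 0.22, TGFBR2 2.30 ± 0.29). WNT modulators rose in 8 of 12 (SFRP4 5.19 ± 0.37, DKK3 4.71 ± 0.33), and ovarian stromal and steroid genes in 9 of 21 with 1 lower (OGN 3.56 ± 0.44, ESR1 -1.60 ± 0.31), and all 3 lists were at adjusted p = 0.163 with an estimated correlation. Versican and hyaluronan genes had 6 of 12 higher and 1 lower (ADAMTS5 3.01 ± 0.26, HMMR -1.42 ± 0.29; adjusted p = 0.161 with an estimated correlation). CD44 was higher by 2.15 ± 0.32, MFAP5 by 2.40 ± 0.59 and FGF1 by 1.17 ± 0.18. TGFB1 was at 0.51 ± 0.10 (adjusted p = 1.66e-05, under 2-fold) and FGF18 at -0.45 ± 0.30 (adjusted p = 0.194).

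Epithelial markers were lower in cancer stroma in 14 of 16 cases (CD24 -2.27 ± 0.48, CDH1, which encodes E-cadherin, -2.21 ± 0.36; adjusted p = 0.158 with an estimated correlation). Serous carcinoma markers were lower in 15 of 20 and higher in 1 (FOLR1 -2.74 ± 0.35, CP -2.28 ± 0.39, SPON1 1.13 ± 0.40). Proliferation genes were lower in 12 of 25 (TOP2A -2.06 ± 0.31, TPX2 -1.84 ± 0.19) and homologous recombination genes in 2 of 9 with 1 higher (CHEK1 -1.36 ± 0.22, XRCC2 1.07 ± 0.22), and all 3 lists were at adjusted p = 0.163 with an estimated correlation. Immediate early genes were higher in 15 of 16 cases (DUSP1 3.35 ± 0.28, CCN1 3.49 ± 0.31; adjusted p = 0.151 with an estimated correlation). Of the other cell types, endothelial markers were higher in 9 of 12 cases (PECAM1 2.96 ± 0.22, VWF 2.68 ± 0.25) and smooth muscle and pericyte markers in 9 of 11 (SYNPO2 4.59 ± 0.39, RGS5 2.98 ± 0.31), both at adjusted p = 0.158 with an estimated correlation. Macrophage markers were higher in 11 of 12 cases (CD14 2.78 ± 0.29, MSR1 2.75 ± 0.27) and complement genes in 7 of 9 with 1 lower (C7 3.48 ± 0.55, C1S 3.03 ± 0.25), both at adjusted p = 0.163 with an estimated correlation. The GAPDH 3′ minus 5′ difference was higher in cancer stroma (1.54 against -0.57, permutation p = 1e-05, the smallest that 100000 resamples can give). With it as a covariate 5098 genes were higher and 789 lower, and HMMR, XRCC2 and FGF18 had the opposite sign. CDH1 (-0.07), CHEK1 (-0.13), TOP2A (-0.76), CD24 (-0.81) and MMP7 (-0.51) no longer passed with this covariate. FOLR1 had the opposite sign without probe sets ending in _x_at or _s_at.

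The series title names a signature specific to cancer-associated fibroblasts, and genes higher in cancer stroma than in both normal stroma and tumor epithelium were therefore counted. There were 1252, against 590 for independent lists and at most 2 in 20 simulations with no effect. The 590 was taken over all 19740 genes, of which those with a small SD could hardly pass either comparison. Among the 9870 genes with an SD above the median SD, 4734 were higher than in normal stroma and 2359 than in tumor epithelium. Independent lists of these sizes over those genes alone would overlap in far more than 590 and not far below 1252. Most of the excess over 590 is thus built in. With the cancer stroma arrays divided between the comparisons (16 and 15 arrays) the median count was 1174.5, from 1022 to 1262. Of the 1252 genes, 250 were also higher than in surface epithelium. The genes with the largest smaller fold change were COL11A1, COL5A2, VCAN, COL3A1, COL6A2, COL1A1, COMP, POSTN, COL8A1, FNDC1, LAMB1 and SLC2A3, most of them collagens and other matrix genes. COL6A2 was higher by 4.64 ± 0.66 than in normal stroma and by 4.34 ± 0.37 than in tumor epithelium. FNDC1 was higher by 4.11 ± 0.69 and 3.96 ± 0.34, LAMB1, a laminin chain, by 3.94 ± 0.59 and 4.10 ± 0.33, and SLC2A3, a glucose transporter, by 3.88 ± 0.49 and 4.34 ± 0.28. Against surface epithelium VCAN was higher by 4.28 and COMP by 5.19, both past the threshold. COL5A2, COL1A1, FNDC1 and SLC2A3 were also among the 250. COL11A1 (1.68, limma adjusted p = 0.184), COL3A1 (1.18, 0.181), COL6A2 (1.60, 0.0958), POSTN (1.52, 0.185), COL8A1 at 0.41 and LAMB1 at -0.31 were not.

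The set held 19 of 27 extracellular matrix genes (1.71 expected, Fisher's exact test adjusted p = 6.28e-16 over 30 lists), 15 of 20 TGF-beta response genes (1.27 expected, 1.72e-13), 13 of 17 markers of activated fibroblasts (1.08 expected, 4.74e-12), 11 of 12 macrophage markers (0.761 expected, 5.44e-12) and 15 of 27 matrix remodelling genes (1.71 expected, 5.04e-11). It also held 11 of 16 immediate early genes (1.01 expected, adjusted p = 1.04e-09) and 6 of 17 interferon response genes (1.08 expected, 0.00186), so it was not limited to fibroblast transcripts. Fisher's test takes genes as independent, which they are not. With an estimated correlation camera called none of these 7 lists against normal stroma (adjusted p = 0.505, and 0.597 for interferon). Against tumor epithelium it called the matrix and TGF-beta response lists alone (0.0483), with 0.0626 for fibroblast markers, 0.129 for matrix remodelling, 0.151 for immediate early genes, 0.163 for macrophage markers and 0.678 for interferon, which had no call with the preset correlation either (0.0725). It held 0 of 16 epithelial, 0 of 20 serous carcinoma and 0 of 25 proliferation genes, which limma had called lower in cancer stroma than in tumor epithelium in 14, 15 and 12 cases. The number of cancer-stroma-specific genes changed with the processing, from 580 with the mean of all probe sets of a gene to 2830 with the GAPDH covariate and 3222 with no fold threshold.

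**Figure D3:**
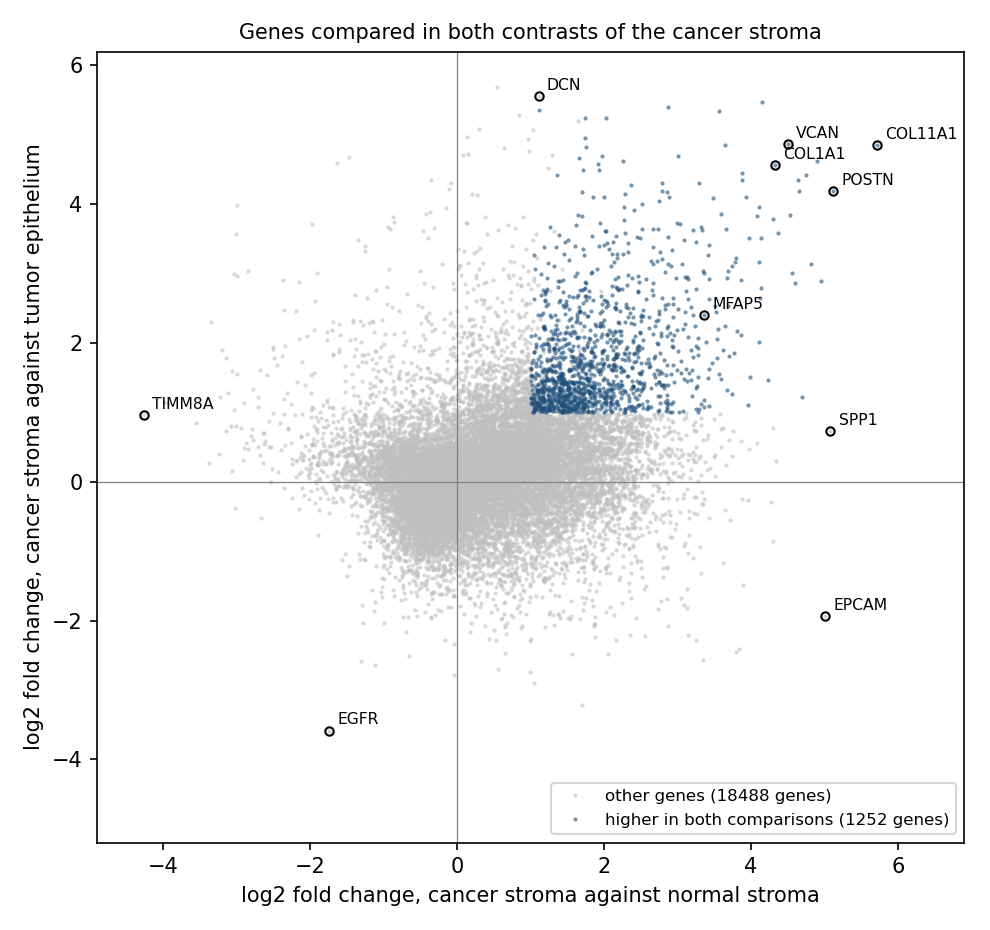
Log2 fold change of 19740 genes (points) between cancer stroma and normal stroma (horizontal axis) and between cancer stroma and tumor epithelium (vertical axis). The 1252 genes that passed as higher in both are dark, among them VCAN (4.50 and 4.87), while EPCAM was higher than in normal stroma and lower than in tumor epithelium.

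The fourth comparison gave the difference between the compartments in ovaries without cancer, as a reference for the third. Markers of the surface layer were lower in the 8 normal stroma arrays than in the 6 surface epithelium arrays: ITLN1 by -9.63 ± 0.18 (log2 fold change ± SE, adjusted p = 6.89e-15 in limma), BNC1 by -8.07 ± 0.14 and CLDN1, a tight junction protein, by -7.86 ± 0.26, each below the surface epithelium median in 8 of 8 arrays. Mesothelial and surface epithelium markers fell in 10 of 14 cases (PRG4 -5.80 ± 0.48; adjusted p = 0.0528 with an estimated correlation), and epithelial keratins fell among 8 of 16 epithelial markers (KRT19 -6.75 ± 0.30, KRT18 -5.52 ± 0.41; camera adjusted p = 0.103). Macrophage markers fell in 11 of 12 cases (MS4A4A -5.04 ± 0.49, CD14 -4.32 ± 0.44) and MHC class II genes in 7 of 9 (HLA-DRA -4.48 ± 0.40, HLA-DPA1 -4.18 ± 0.41). Complement genes fell in 7 of 9 (CFB -6.12 ± 0.21, C3 -5.87 ± 0.43), and all 3 lists were at adjusted p = 0.744 with an estimated correlation. In all 5 lists the counts adjusted over the list alone were the same. Among the genes with an SD above the median SD, 12 lists were called, all up, and the 4 calls made over all genes, all down, were lost. TMEFF2, a membrane protein (6.14 ± 0.23), MEIOC (5.44 ± 0.36) and TIMM8A (5.44 ± 0.19) were the largest rises, and CYP19A1 rose by 4.63 ± 0.31.

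Of 27 extracellular matrix genes, 6 were higher and 9 lower in normal stroma (THBS1 3.09 ± 0.70, COL11A1 -4.03 ± 0.42; camera adjusted p = 0.846), and the median of this list changed sign after a further quantile normalization. TGFBR2 fell by 2.52, CD44 by 3.48, FGF18 by 1.96 and FGF1 by 3.31 on the log2 scale, and VCAN (-0.23 ± 0.79, adjusted p = 0.798), MFAP5 (-0.54 ± 0.62, 0.431) and TGFB1 (-0.12 ± 0.21, 0.596) did not pass. MFAP5 passed with the hybridization spikes as a covariate (-5.34). The spikes separated these groups without overlap (1.07 to 1.99 against -0.18 to 0.31), so that fit cannot tell the groups from the spikes. Of 19740 genes, 2478 were higher and 6562 lower. The median of all genes was -0.07, and its sign depended on the processing: it was -0.24 with array medians set to 0, 0.11 with the mean of all probe sets of a gene, 0.18 without probe sets ending in _x_at or _s_at, and -1.42 among the genes with an SD above the median SD. The GAPDH 3′ minus 5′ difference separated both groups without overlap (1.78 against -1.06, exact permutation p = 3.33e-04, the smallest that 8 against 6 arrays can give). With it as a covariate limma called 0 genes higher (574 at an unadjusted p under 0.05) and 5 lower, while many fold changes stayed large (TMEFF2 5.91, TIMM8A 4.95, CLDN1 -6.57, MS4A4A -6.73, C3 -9.66) and some did not (KRT19 -3.49, COL11A1 -0.60). Without overlap the covariate fit cannot separate the groups from that difference, so the lost calls speak neither for nor against it. CFB and TGFB1 had the opposite sign without probe sets ending in _x_at or _s_at. With the mean of all probe sets of a gene TGFBR2 (-0.78), CD44 (-0.43) and FGF18 (-0.06) no longer passed.

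**Figure D4:**
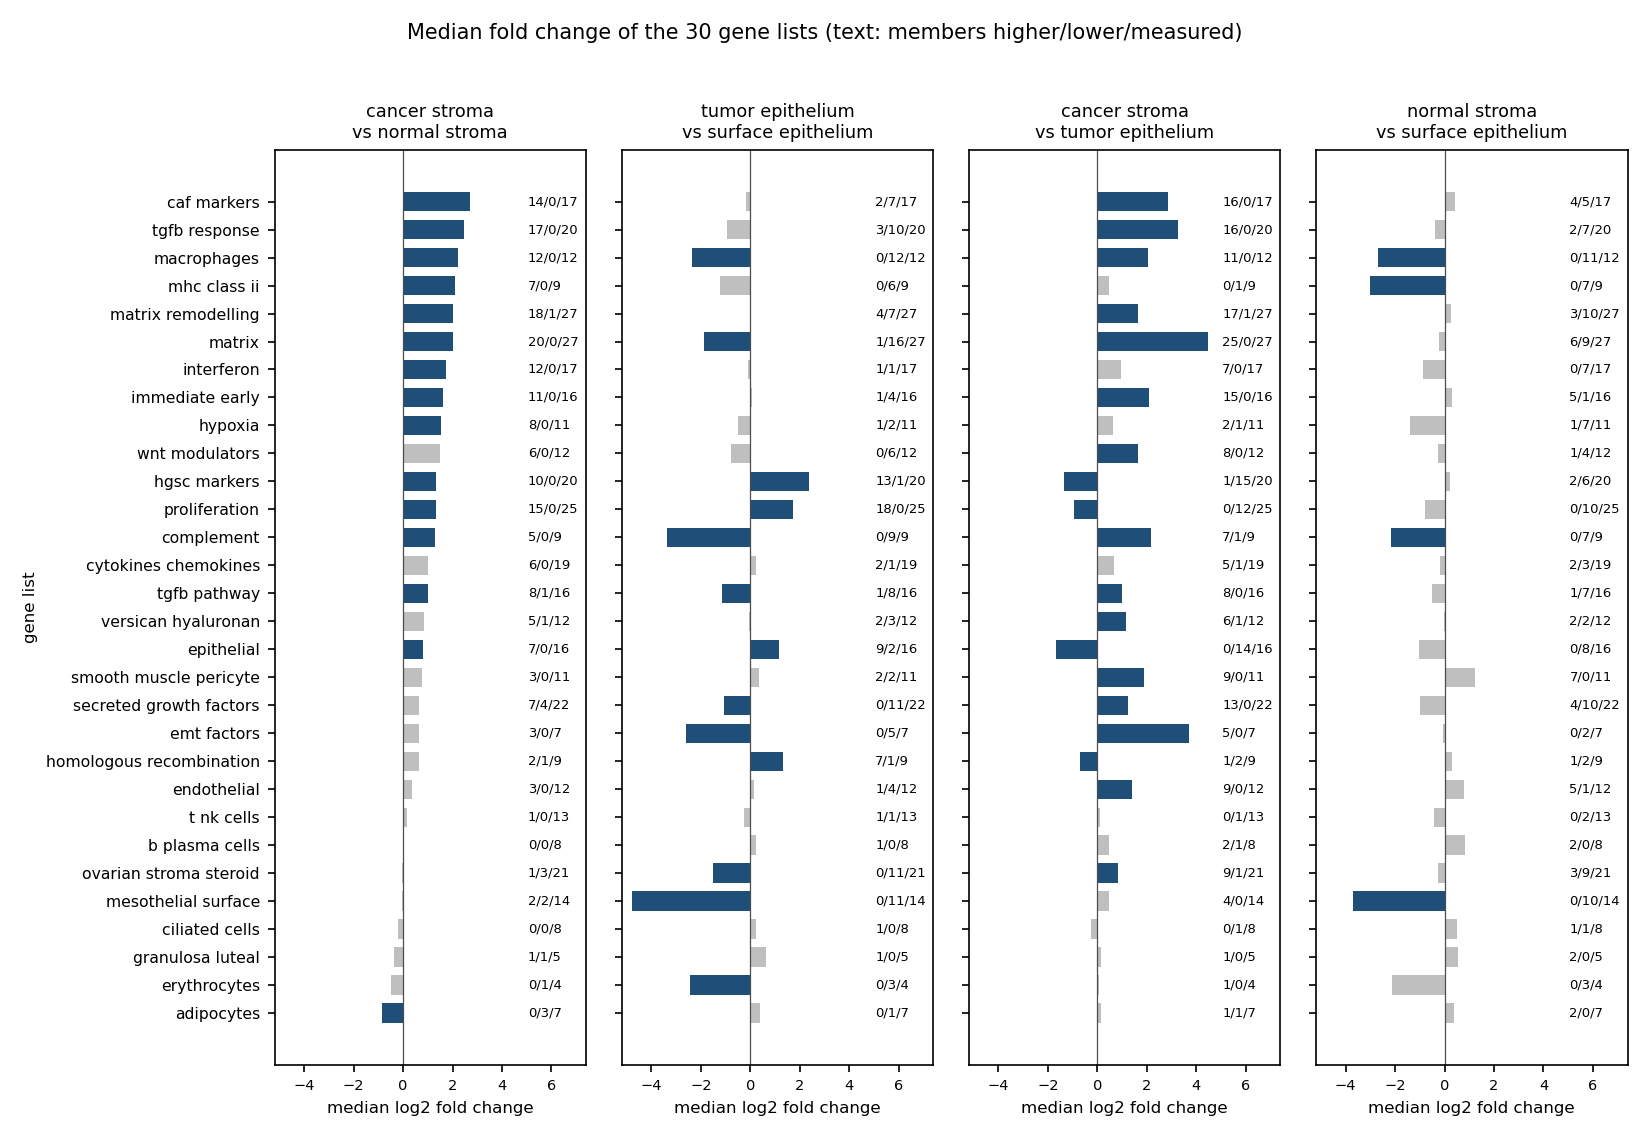
Median log2 fold change of the measured members of the 30 gene lists in 4 comparisons, with the numbers of members higher, lower and measured beside each bar; dark bars had a camera call with the preset correlation. Extracellular matrix genes were higher in cancer stroma in both of its comparisons (20 and 25 of 27).

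The cancer-normal differences of stroma and epithelium were then tested against each other in 1 model. A positive value means that cancer minus normal was more positive in stroma, which a fall in epithelium alone can also give. It was positive for COL8A1 (9.21 ± 1.00, log2 difference ± SE, adjusted p = 2.81e-12 in limma over 77 arrays), COL11A1 (8.88 ± 1.24), TGFBR2 (4.81 ± 0.69) and VCAN (5.09 ± 0.99). The largest values were for the surface epithelium transcripts BCHE (10.24 ± 0.98) and ITLN1 (9.95 ± 0.26), which fell in epithelium (-8.30 and -9.99), followed after COL8A1 by RARRES1 (8.96 ± 1.11) and ARHGAP18 (8.94 ± 0.57). It was negative for NEK2, a mitotic kinase (-4.64 ± 0.50), TIMM8A (-4.47 ± 0.56), EGFR (-4.30 ± 0.75), CYP19A1 (-4.23 ± 0.45) and RALGAPA2 (-4.13 ± 0.40). Of these, TIMM8A, CYP19A1 and RALGAPA2 fell in stroma (-4.27, -3.25 and -3.37). Of 19740 genes, 7512 had a positive and 3427 a negative value. The median of all genes was 0.24, and its sign depended on the processing: it was 0.39 with array medians set to 0, 0.09 after a further quantile normalization, -0.03 with the mean of all probe sets of a gene and -0.11 without probe sets ending in _x_at or _s_at. Among the genes with an SD above the median SD it was 1.895.

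Among the lists, 24 of 27 extracellular matrix genes had a positive value, as did 15 of 20 TGF-beta response genes (POSTN 7.79 ± 1.19) and 11 of 17 markers of activated fibroblasts (SULF1 7.30 ± 1.04; 10 adjusted over the list alone). So did all 12 macrophage markers (MS4A4A 7.18 ± 0.81, CD14 7.11 ± 0.70) and all 9 complement genes (C3 7.34 ± 0.70). Camera called these up, and with an estimated correlation the adjusted p was 0.607 for the matrix, TGF-beta response and macrophage lists, 0.620 for the fibroblast markers and 0.50 for complement. Mesothelial and surface epithelium markers had 12 of 14 positive and 1 negative (DAB2 7.05 ± 0.51, KRT5 -1.17 ± 0.36), the only call of the 10 that held with an estimated correlation (adjusted p = 1.39e-04). Among the genes with an SD above the median SD, 4 lists were called up and 6 down, and the calls of the fibroblast markers and TGF-beta response genes were lost. CD44 (5.63 ± 0.85), FGF1 (4.48 ± 0.44), MFAP5 (2.94 ± 1.39, adjusted p = 0.0488) and FGF18 (1.52 ± 0.71, 0.0485) had a positive value, and TGFB1 was at 0.63 ± 0.25 (0.0199, under 2-fold). MFAP5 and FGF18 did not pass with the 2 closest cancer stroma arrays averaged (2.84 and 1.45), with the GAPDH covariate (2.72 and 1.32), after a further quantile normalization (1.64 and 0.15) or with the mean of all probe sets of a gene (2.24 and -0.011). In the last setting EGFR (-0.86), RALGAPA2 (-0.46) and CD44 (0.76) did not pass either, and MFAP5 (2.28) did not without probe sets ending in _x_at or _s_at. Across the 19740 genes, which are not independent replicates, the cancer-normal differences of stroma and epithelium had a Pearson r of -0.350 and a Spearman rho of -0.474, and Pearson's r was -0.0797 among the genes with an SD above the median SD. Genes higher in cancer stroma and lower in tumor epithelium numbered 2089 (1099 expected from independent lists), while 175 were higher in both (348 expected) and 151 lower in both (195 expected). These expected numbers were taken over all 19740 genes. Among the 9870 genes with an SD above the median SD, 4734 were higher in cancer stroma and 4276 lower in tumor epithelium. Independent lists of these sizes over those genes alone would overlap in nearly as many genes as the 2089. Most of the excess of the 2089 over 1099 is thus built in, and it does not by itself show opposite changes.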

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

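Of the tests on the patterns below, 4 were chosen only after the result was seen: those of tumor cells as the source of the matrix transcripts, of an array-wide shift, and of the hybridization spikes and the GAPDH 3′ minus 5′ difference as the cause of the excess of higher genes. For the epithelial markers the limits of the spike test were set beforehand, and its explanation was narrowed to the whole cause after its result was seen. For each gene count, 100 splits of the arrays into groups of the same sizes were taken, the real one included, and 1 of 100, the real one, gave as many genes in each case. For the 5 comparisons this argues against a chance split of the arrays, though 1 in 100 is the smallest share that 100 splits can show. The real count and the highest of the other splits were 5723 and 1440 for cancer stroma against normal stroma, 5874 and 365 for tumor against surface epithelium, 3160 and 656 for cancer stroma against tumor epithelium, and 9040 and 4295 for normal stroma against surface epithelium. They were 10939 and 2332 for the difference of the cancer-normal differences, and 1252 and 0 for the genes higher in cancer stroma in both comparisons. For this last count each comparison was split on its own, so the arrays taken as cancer stroma differed between them. The 0 therefore does not speak to an overlap brought by shared arrays. For the number of gene lists called by camera with the preset correlation chance cannot be excluded. In the same order of the first 5 comparisons, 9, 16, 6, 63 and 38 of the 100 splits called as many lists, with 15, 13, 19, 4 and 10 lists in the real split and 17, 24, 21, 13 and 20 at most in the others.

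Of the epithelial and serous carcinoma markers, 17 were higher in cancer stroma than in normal stroma. A trend with the hybridization spikes as the whole cause is argued against, since 14 of them still passed with the spikes as a covariate. Tumor cells captured in the stroma regions stay open as a candidate source: across the 28 paired specimens, the mean r of these genes between stroma and its own tumor epithelium was 0.307, above the 95th percentile of 10000 shuffled pairings (0.151; highest 0.346), and their median was 1.74 lower in stroma than in tumor epithelium (-1.74). That correlation was not particular to tumor cell transcripts, with a mean r of 0.214 over the other 4845 genes higher in cancer stroma and 0.416 over the matrix and fibroblast genes. Of the 33 matrix and fibroblast genes higher in cancer stroma, 31 were also higher than in tumor epithelium, which argues against tumor cells as their source, and a difference of the stroma with the disease stays open as untested.

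Of the 5723 genes that passed between cancer and normal stroma, 85.0% were higher in cancer stroma, as were 82.9% of the probe sets with 1 symbol that passed (6815 higher and 1410 lower), while among the 13522 probe sets without exactly 1 gene symbol, which the comparisons left out, the direction was reversed (711 higher and 1800 lower, 28.3% higher). With array medians set to 0 the share was 87.4%. This decides little on an array-wide shift, because the mean array medians lay close together (0.016 in cancer and 0.073 in normal stroma). Setting them to 0 could therefore hardly move the share. With the hybridization spikes as a covariate the share was 85.9%, but the share moved little in any setting (80.2% to 89.6%) and so decides little. With this covariate 3937 genes were higher and 644 lower, and 3816 of the 4862 higher genes still passed. That argues against a trend with the spikes as the whole cause. The 85.0% with the GAPDH 3′ minus 5′ difference as a covariate decides nothing, because the groups hardly differed in it (1.78 in normal and 1.54 in cancer stroma, permutation p = 0.581). Poorer RNA or lower input in normal stroma stays open, since its arrays had lower GAPDH 3′ (-2.10 against 0.05), GAPDH 5′ (-3.88 against -1.497, adjusted p = 4.80e-04) and 18S signals (-2.36 against 0.02, adjusted p = 3.27e-05) and a higher SD (0.962 against 0.746, adjusted p = 0.00525). Across the 32 tumor epithelium arrays, which are outside the comparison, the mean of the lower minus that of the higher genes rose with the GAPDH 3′ minus 5′ difference (r = 0.775, permutation p = 3.00e-05, adjusted p = 1.00e-04; rho = 0.472, permutation p = 0.00725, adjusted p = 0.0181, over 10 relations; r = 0.460 without the 2 farthest). This mean difference was 3.06 in normal stroma (2.19 to 3.95) and -0.16 in cancer stroma, where it reached 3.17. Its genes were picked by the comparison of these 2 groups, so the gap between the groups was fixed in advance. Over all genes the cancer-normal difference had r = -0.699 with the slope on the GAPDH 3′ minus 5′ difference within cancer stroma, whose arrays enter both. With the slope within tumor epithelium r was -0.515, and -0.380 without its 1 array with an SD over 0.9. The stroma groups hardly differed in the GAPDH difference, so these slopes do not show that it brings the excess. Part of the excess may still come from RNA quality in other respects. A difference of the stroma with the disease also stays open as untested.

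All 12 macrophage markers and 3 of 4 red cell markers were higher in surface epithelium than in tumor epithelium. Blood in the surface epithelium samples is a candidate source: the mean of 12 neutrophil markers was 1.14 higher in surface epithelium (2-sided exact permutation p = 2.28e-05, 6 against 32 arrays), with S100A8 at 4.28, FCGR3B at 2.93 and CXCR2 at 1.78, while CSF3R was at 0.23 and CXCR1 at -0.34. S100A8 is also expressed by epithelial and monocytic cells, and T and NK cell markers, which blood would also bring, differed by 0.23 (exact permutation p = 0.327). Macrophages collected with the surface layer cannot be told apart from this with 6 arrays, in which the macrophage and the surface marker means had r = -0.00162 (exact permutation p = 0.997; rho = 0.0857, 0.919; r = 0.472 without the 2 farthest). The tissue around the surface layer was not tested as a biological explanation.

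In the groups of 8 and 6 arrays, 114 values were tested for an array far from the others, and 11 were found, where chance gives about 1 in 20. The gap of the highest normal stroma array to the next, as a part of the group's range, was 0.570 for the mean of the TGF-beta response genes, 0.796 for versican and hyaluronan genes, 0.623 for secreted growth factors, 0.635 for proliferation genes, 0.665 for endothelial markers, 0.855 for adipocyte markers, 0.638 for VCAN, 0.734 for CD44 and 0.565 for FNDC1. In surface epithelium it was 0.643 for the GAPDH 3′ control and 0.651 for proliferation genes.

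By the test of the difference itself, cancer minus normal was more positive in stroma than in epithelium for 7512 genes and more negative for 3427, whichever compartment changed. The most positive values were 10.24 for BCHE, 9.95 for ITLN1, 9.21 for COL8A1, 8.96 for RARRES1 and 8.94 for ARHGAP18, and the most negative were -4.64 for NEK2, -4.47 for TIMM8A, -4.30 for EGFR, -4.23 for CYP19A1 and -4.13 for RALGAPA2.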

How the results depend on the processing

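The array medians set to 0, the SD filter, the exclusion of 4 arrays, the averaged pair and the hybridization spikes were chosen after seeing the data. The cause of the changes below was not tested, except that fewer genes or a changed threshold act by construction. With the mean of all probe sets of a gene, the counts were 2541 higher and 354 lower for cancer against normal stroma, 919 and 2419 for tumor against surface epithelium, 1163 and 387 for cancer stroma against tumor epithelium, 4143 lower for normal stroma against surface epithelium, and 580 cancer-stroma-specific genes (150 also higher than surface epithelium). VCAN was at 0.15 in tumor against surface epithelium and at 0.062 in normal stroma against surface epithelium, where TGFB1 was at 0.28. The FGF18 difference of differences was -0.011. Without probe sets ending in _x_at or _s_at, 3136 genes were higher in cancer than in normal stroma, 815 were cancer-stroma-specific genes, and 9 lists (cancer against normal stroma) and 2 lists (normal stroma against surface epithelium) were called. ELMOD2 was at 1.11, LTBP3 at -0.83, CXCL14 at -1.90, MCAM at -0.42, CFB at -1.24 and TGFB1 at -0.46 between the stroma groups. FOLR1 was at -1.53 and HBB at 0.71 in tumor against surface epithelium, FOLR1 at 1.45 in cancer stroma against tumor epithelium, and CFB at 1.097 and TGFB1 at 0.68 in normal stroma against surface epithelium. The TGFB1 difference of differences was -0.39. After a further quantile normalization 2452 genes were lower in tumor against surface epithelium and 1389 in cancer stroma against tumor epithelium. VCAN was at 0.64 and MFAP5 at 0.16 in normal stroma against surface epithelium. Array weights gave 2133 cancer-stroma-specific genes (540 with surface epithelium). The GAPDH covariate, which the groups do not share in range for normal stroma and surface epithelium, gave 5098 genes higher in cancer stroma than in tumor epithelium. It gave 0 higher (limma; 574 at an unadjusted p under 0.05) and 5 lower in normal stroma against surface epithelium, and 2830 cancer-stroma-specific genes (626 with surface epithelium). HMMR was at 0.14, XRCC2 at -0.12 and FGF18 at 0.13 in cancer stroma against tumor epithelium. VCAN was at 0.16 and FGF18 at 0.45 in normal stroma against surface epithelium. With the hybridization spikes as a covariate, 1564 genes were higher and 2682 lower in normal stroma against surface epithelium. MFAP5 was at -0.99 in tumor against surface epithelium and XRCC2 at -0.83 in cancer stroma against tumor epithelium. Among genes with an SD above the median SD, 549 were lower in cancer than in normal stroma, 794 higher in tumor than in surface epithelium, and 775 higher in normal stroma than in surface epithelium. Of these genes, 848 had a negative difference of differences, 12 lists were called for normal stroma against surface epithelium (12 up and 0 down, none of the 4 called over all genes), and in the agreement of the cancer-normal differences in stroma and epithelium Pearson's r was -0.0797. Without the 4 broad cancer arrays, 394 of the cancer-stroma-specific genes were also higher than surface epithelium. With no fold threshold, 4127 genes were lower in cancer than in normal stroma, 6882 higher and 6954 lower in tumor against surface epithelium, and 7224 and 5329 in cancer stroma against tumor epithelium. Then 7273 were higher in normal stroma against surface epithelium, 6860 had a negative difference of differences, and 3222 were cancer-stroma-specific genes (484 with surface epithelium). Treat gave 2714 genes higher between the stroma groups and 705 cancer-stroma-specific genes (67). Camera with an estimated correlation called 0 lists for cancer against normal stroma (0 at an unadjusted p under 0.05; fry 23) and 0 for normal stroma against surface epithelium (2; fry 19). It called 1 for tumor against surface epithelium, 3 for cancer stroma against tumor epithelium and 1 for the difference of differences (fry 24).

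Leaving out each normal array in turn kept every count within 1.5 times: 4443 to 5038 higher and 764 to 949 lower between the stroma groups, 1325 to 1488 and 4314 to 4577 in tumor against surface epithelium, 2329 to 2611 and 6349 to 6706 in normal stroma against surface epithelium, 7339 to 7589 and 3284 to 3548 for the difference of differences, and 1127 to 1285 cancer-stroma-specific genes (205 to 257). Without a replicate block 2404 genes were higher and 760 lower in cancer stroma against tumor epithelium, and with a fixed replicate block over the paired specimens 2325 and 774. A filter at the 75th percentile of an array could not be made on centred values, and the signal over background is not known.

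Besides the named genes given in the report, those that kept their sign and no longer passed were the following. Between the stroma groups they were P4HA3 (-0.91), TGFBR3 (-1.46), CCL5 (1.31), PRRX1 (1.83), ADH1B (-2.33), ACTG2 (1.95) and TGFBR2 (1.204) with the spikes, CCL5 (1.199), ADH1B (-2.28), CD24 (1.87) and WFDC2 (1.26) after a further quantile normalization, P4HA3 (-0.99) with array medians set to 0, and ADH1B (-2.36) without the 4 broad arrays. In tumor against surface epithelium they were COMP (0.14), LTBP1 (1.26) and CDK1 (1.51) with the spikes, COMP (0.94) and RAD51C (-0.86) with the GAPDH covariate, RAD51C (-0.68) after quantile normalization and COMP (0.93) with medians set to 0. In cancer stroma against tumor epithelium they were MMP7 (-0.94), HMMR (-0.35), CD24 (-1.297), CDH1 (-0.84), SPON1 (0.74), TOP2A (-1.196), TPX2 (-0.91) and CHEK1 (-0.58) with the spikes, SPON1 (0.81) and XRCC2 (0.97) after quantile normalization, and XRCC2 with array weights (0.87) and without the broad arrays (0.97). In normal stroma against surface epithelium COL11A1 (-3.52), THBS1 (3.395), CD44 (-6.698) and FGF18 (-2.63) lost their calls with the spikes at fold changes near or above those without. So did 19 of 25 with the GAPDH covariate, many at fold changes as large (HLA-DRA -5.87, CFB -6.82). Neither covariate overlapped between these groups, so these lost calls decide nothing.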

Other observations

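The test of RNA quality and that of the TGF-beta response genes below were set before their results were seen, while the partial correlation was chosen after, and the RNA quality test was read more cautiously after, because its r did not lie within the bounds by more than its spread. Across the cancer stroma arrays, with the 2 closest averaged (30 values), VCAN rose with the mean of the other 19 TGF-beta response genes (r = 0.843, permutation p = 1e-05, the smallest that 100000 resamples can give; rho = 0.875, permutation p = 1e-05; adjusted p = 5.00e-05 for both over 10 relations; r = 0.803 without the 2 farthest arrays). This r lay at the 99.7 percentile of all genes, whose median r was 0.05, so VCAN may share its variation with these genes. It is not particular to VCAN, since MFAP5 lay at the 98.7 percentile, FAP at 98.5 and TGFBR2 at 98.3, while TGFB1 lay at 59.0. Of the 20 measured response genes, 13 also stood in other lists. VCAN itself had r = 0.463 with TGFB1 (permutation test, adjusted p = 0.0210; rho = 0.356, adjusted p = 0.0896). With TGFBR2 it had r = 0.462 (permutation test, adjusted p = 0.0210; rho = 0.580, adjusted p = 0.00377). VCAN had r = -0.169 with the GAPDH 3′ minus 5′ difference (permutation p = 0.368, adjusted p = 0.459; rho = -0.285, permutation p = 0.126, adjusted p = 0.157; r = -0.194 without the 2 farthest), which does not exclude a relation. The response mean itself fell with that difference (r = -0.375, permutation p = 0.0405, adjusted p = 0.0674; rho = -0.364, permutation p = 0.0475, adjusted p = 0.0896; r = -0.362 without the 2 farthest). Given that difference, the partial r of VCAN and the response mean was 0.853, which argues against a trend with it as the whole cause of their relation, while poorer RNA in other respects stays open.

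The 2 closest cancer stroma arrays had an SD of the difference of 0.304 over the probe sets and r = 0.917. The next closest pair had r = 0.797, and over all cancer stroma pairs the median r was 0.253 and the median SD of the difference 0.863. The tumor epithelium arrays with the same sample numbers differed with an SD of 0.784 and had r = 0.142, at rank 442 among the epithelial pairs. Both stroma arrays entered the main comparisons as separate samples.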
